A study of Drosophila melanogaster with 2 samples.

How the data were processed

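Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of the disco protein in Drosophila melanogaster embryos collected 0 to 8 h after egg laying. Per the labels' protocols, embryos were homogenised in 1.8% formaldehyde for 15 minutes and the chromatin was sonicated for 15 minutes. Antibody-bound chromatin was pulled down with Protein A beads, and an aliquot of the same chromatin was kept as the input. The series has 2 samples. One is the disco ChIP, whose title names ChIP replicates 1 and 2 together, and the other is the input chromatin. The series design gives the input as the control for the ChIP.

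One processed table, the peak list of the ChIP sample, was analysed. No processed table of the input was analysed here. Reads were aligned with Bowtie to the BDGP5 assembly (Release 5), per the submitters' processing notes. Peaks were called with MACS, per the file headers. Versions, the read length, the way the input entered the calls and the calling threshold are not given in the sources used here. Whether the replicates were pooled before calling or combined afterwards is also not given in the sources used here. Each line of the list holds a chromosome, a start, an end, a peak name and one score. The peak names are numbered from 1 to 1723 and no number is missing. The score deposited by the authors is the peak caller's own value, and its scale is not named in the header. The lowest score is 50.09, close to a round value, as a list cut at a fixed p-value would have if the score were minus 10 times the log10 of that value, which is how MACS can write it. On that reading, which no header or label states, the score would measure the significance of a peak and not the amount of binding. The score was used only to describe, rank, filter and compare peaks within this list. Since its scale is not named, a difference between scores is not a fold of signal, and no ratio of scores is given. The depth is unknown, since the list gives no read counts, so no counting interval could be set on any single peak. The deposited starts were read as counting from 0, and 1 was added for every start printed.

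With 1 list for both replicates, no spread between replicates could be computed. No ChIP value was tested against the input beyond the authors' own peak calls. Intervals on shares of peaks are 95% Wilson binomial intervals, which treat peaks as independent and cover counting error only.

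The number, width and score of the peaks were described first. Peaks with a gap under 1 kb were then merged for the counts per chromosome arm. The lengths of the Release 5 arms were not used here, so counts per Mb refer to the span between the first and last peak midpoint of an arm. Clustering was tested on the 5 large arms (2L, 2R, 3L, 3R and X). The 2 measures were the median distance between neighbouring peak midpoints and the share of peaks with another midpoint within 10 kb. Each was set against 10000 random placements of the same number of midpoints between the first and last peak of the same arm, in a two-sided permutation test whose smallest possible p is 0.0002. Correlations across peaks and differences in medians were tested with 100000 resamples. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

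The tests were run first on simulated data, with fewer placements and resamples than were used for the peak list. In 20 simulated sets of 1716 uniformly placed peaks the clustering test made 0 calls at 0.05. Such sets meet the test's own assumption of even density, so they do not show how it behaves where density is uneven. In 20 sets in which 10% of the peaks were placed close to another it made 20. The permutation test of medians made 0 calls in 20 sets of shuffled scores and 20 in 20 sets in which the scores on the X were raised by 10.

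The clustering test, the counts per arm, their settings and the rule for what is named were fixed before the data were examined. Counts per Mb of span, score against width, the counts in 1 Mb windows, and the tests and settings named as later choices in the closing section were added afterwards. The rule for a list without an annotation of its own build names the 20 highest-scoring peaks and the 5 groups with the most peaks, by position, where neighbours in a group lie within 10 kb. The 1 gene table used here is of Release 6, and coordinates were not moved between releases. The planned comparisons of peaks with transcription starts, introns and exons, gene lists and sequence motifs were therefore not run, and no peak is assigned to a gene. The table was used only for the names of disco and disco-r and the chromosome they lie on. The alternatives tried were the top 50% and the top 25% of peaks by score, merged against unmerged peaks, covered bases in place of counts, neighbour limits of 5 and 50 kb and, chosen after seeing the data, other schemes of random placement.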

Results

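The series mapped where disco binds the genome of the early fly embryo. The gene disco (disconnected, locus tag Dmel_CG9908) encodes a zinc finger protein known for its role in the larval visual nerve and, together with its relative disco-r (Dmel_CG32577), in the gnathal segments of the head and in the ventral appendages. Both genes lie on the X. The antibody is named for disco in the labels, and the chromatin came from untreated embryos of 0 to 8 h. The data analysed are 1 list of ChIP peaks for 2 ChIP replicates combined, with chromatin input as the study's control. The read depth behind the list is unknown. All positions are on Release 5 (BDGP5), counted from 1, and every score is the value given by the authors' peak caller, which may be a measure of significance, not of the amount of binding. No peak is assigned to a gene, exon, intron or UTR, because no annotation of this release was used here.

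The disco ChIP gave 1723 peaks, of which 1716 (99.6%) lay on the 5 large chromosome arms 2L, 2R, 3L, 3R and X. Together the peaks covered 3.07 Mb. The median peak was 1529 bp wide, with quartiles of 1111 and 2155 bp and extremes of 481 and 8688 bp. Scores were concentrated just above the lowest value: the minimum was 50.09, the median 68.69 and the upper quartile 91.2. A score above 100 was reached by 324 peaks, or 18.8% of the list (95% Wilson interval 17.0 to 20.7%). Only 17 peaks scored above 200 and 6 scored above 300. No peak overlapped its neighbour. There was no replicate against which the spread of a single score could be set, so the ranking below is a description of this list.

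The highest-scoring peak of the list lay on the X at 16110278 to 16112258, with a score of 748.23. It was 1981 bp wide, which placed it at rank 550 by width. The nearest other peak, at X 16097042 to 16098134, had its midpoint 13.7 kb away and a score of 81.45. A group of 4 peaks at X 16041418 to 16049734, with a highest score of 114.32, lay farther to the same side. The second highest-scoring peak, on 2L at 6976797 to 6983514, scored 508.17 and was the third widest of the list at 6718 bp. The third, on 3R at 24924009 to 24932696, scored 321.52 and was the widest at 8688 bp. The remaining peaks above 300 lay on 3R at 13515157 to 13519284 (score 313.88), on 3R at 22951193 to 22953554 (score 310.59) and on 2L at 19166658 to 19171600 (score 303.07).

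The next 7 in rank had scores between 219.36 and 252.09. They lay on 2L at 6418897 to 6422048, on 3R at 9571382 to 9573674, on 3R at 12082395 to 12085461, on 3L at 5848751 to 5851330, on 3R at 15859868 to 15862066, on 3L at 16005242 to 16006400 and on 2R at 9068199 to 9070798. The last 7 of the 20 highest-scoring peaks had scores between 191.8 and 218.57. They lay on 3L at 14004423 to 14007692, on 2R at 17224708 to 17228874, on 3R at 25627455 to 25633972, on 2R at 16715248 to 16718541, on 2R at 11621483 to 11623771, on 2R at 19411452 to 19415257 and on 2R at 16890015 to 16894021. Of these 20 peaks, 7 were on 3R, 6 on 2R, 3 each on 2L and 3L, and 1 on the X. Their median width was 3211 bp, and 19 of the 20 were wider than the median of the whole list.

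**Figure D1:**
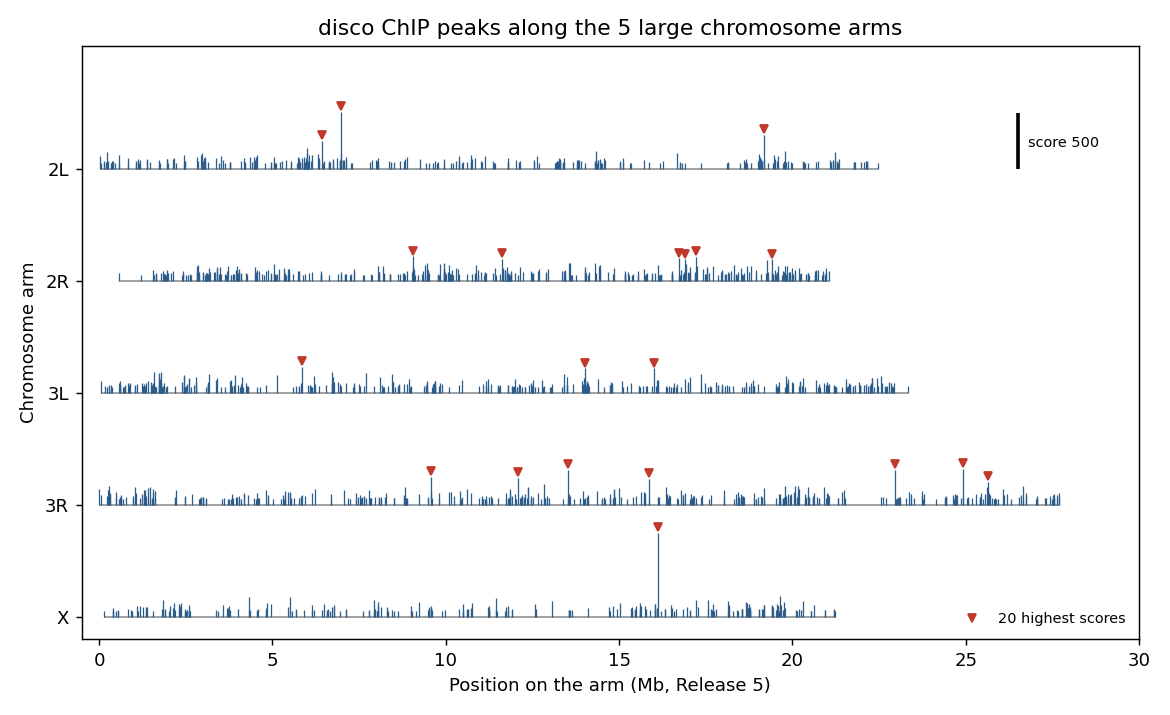
Each vertical line is a disco ChIP peak at its midpoint (x axis, Mb on Release 5) on 1 of the 5 large arms (y axis), with a height in proportion to its score; the bar at the upper right stands for a score of 500 and red triangles mark the 20 highest scores. The highest-scoring peak, on the X, scored 748.23, and 7 of the 20 marked peaks lie on 3R.

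Wider peaks had higher scores. The median score was 59.04 in the narrowest 20% of the list (345 peaks, up to 1020 bp) and 85.22 in the widest 20% (345 peaks, from 2356 bp). Across the 1723 peaks Spearman's rho was 0.38, with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. This is a correlation across peaks of 1 list, and peaks are not independent replicates. Width and score were also set by the same peak calls, so the correlation says nothing on its own about binding. Of the 20 highest-scoring, the peak on 3L at 16005242 to 16006400 was the narrowest at 1159 bp, and the highest-scoring peak, on the X, was the next narrowest at 1981 bp.

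**Figure D2:**
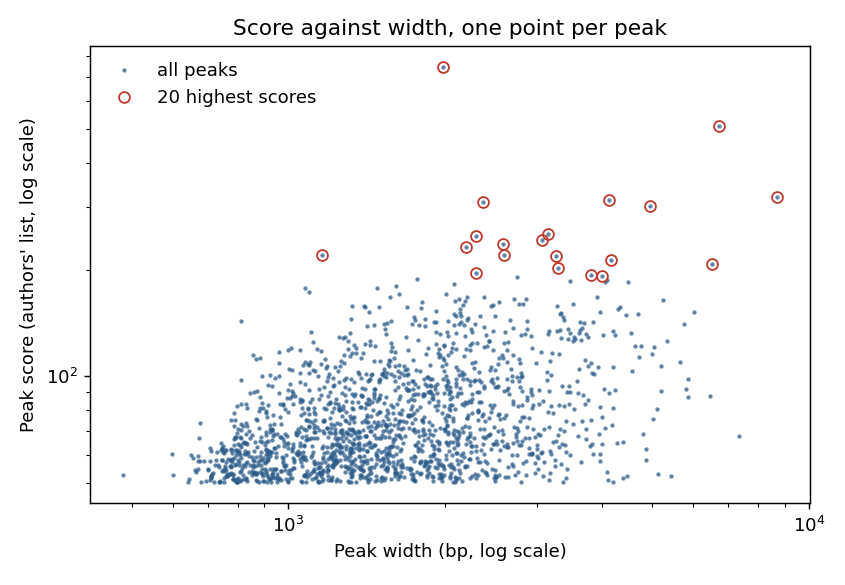
Each point is 1 of the 1723 peaks, with its width in bp on the x axis and its score on the y axis, both on log scales; red circles mark the 20 highest scores. The highest point, at 1981 bp and 748.23, is the peak on the X, and 19 of the 20 circled peaks lie to the right of the median width of 1529 bp.

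The distribution over the chromosome arms was compared next. After peaks with a gap under 1 kb were merged, 1623 regions remained on the 5 large arms. Arm 3R held 397 of them (24.5%, 95% Wilson interval 22.4 to 26.6%), 3L held 358 (22.1%, 20.1 to 24.1%) and 2R held 354 (21.8%, 19.9 to 23.9%). Arm 2L held 282 (17.4%, 15.6 to 19.3%) and the X held 232 (14.3%, 12.7 to 16.1%). Per Mb between the first and last peak of the arm, this was 17.3 regions on 2R, 15.4 on 3L, 14.3 on 3R, 12.6 on 2L and 11.0 on the X. No test against the arms' full lengths was made. The median score ranged from 67.52 on 3L to 71.19 on 2R and was 68.1 on the X. Peaks on the X had a median width of 1320.5 bp, against 1515.5 to 1666 bp on the autosomal arms. The X held 12.2% of the bases covered on the 5 arms, below the interval of its share of regions.

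Outside the large arms there were 7 peaks. Chromosome 4 held 2, at 426605 to 427687 (score 52.87) and 432281 to 433059 (score 57.33). The unplaced sequence set Uextra held 3, with scores of 52.47, 52.84 and 77.86. The heterochromatic sequences 3LHet and XHet held 1 each, with scores of 51.36 and 76.39.

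Peaks of disco lay in groups more often than random placement gives. Another peak midpoint lay within 10 kb for 714 of the 1716 peaks on the large arms (41.6%, 95% Wilson interval 39.3 to 44.0%). The 714 peaks lay in 303 groups and are not independent of each other, so this interval is likely too narrow. Random placement gave a median of 26.2%, with a central 95% of 23.5 to 29.0% and a highest value of 31.7% (two-sided permutation p = 0.0002, the smallest that 10000 placements can give). The median distance between neighbouring midpoints was 30.7 kb, against 45.7 kb (43.4 to 48.0 kb) at random, with the same p. With a limit of 5 kb the share was 21.9% against 14.1% at random, and with 50 kb it was 84.6% against 77.6%. The random placements used the span between the first and last peak of each arm and took no account of sequence to which reads cannot be aligned.

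**Figure D3:**
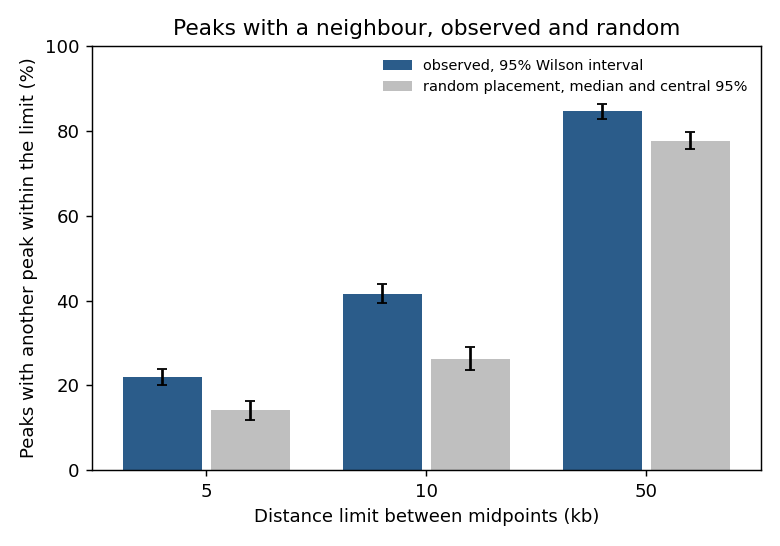
Bars give the percentage of the 1716 peaks on the large arms (y axis) with another peak midpoint within 5, 10 or 50 kb (x axis), observed with 95% Wilson intervals (blue) and as the median and central 95% of 10000 random placements (grey). The Wilson intervals treat peaks as independent, which neighbouring peaks are not. At 10 kb the observed share was 41.6% and the random median 26.2%.

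Chaining midpoints within 10 kb of each other gave 1002 single peaks, 222 pairs, 59 groups of 3 and 22 groups of 4 or more. The group with the most peaks lay on 3L at 1772289 to 1802916 and held 6, with a highest score of 184.45. Groups of 5 lay on 3L at 6723500 to 6744340 (highest score 190.94), on 2R at 4503914 to 4527885 (127.5) and on 2R at 19899411 to 19926913 (84.6). Among the 18 groups of 4, the one on 2L at 6970021 to 6985044 had the highest score, since it holds the second highest-scoring peak of the list. The group of 4 on 2R at 9060261 to 9075923 and the one on 3L at 14000340 to 14018880 also hold peaks from the 20 highest-scoring ones. Groups of 4 on 3L at 1713417 to 1722778 and at 1748593 to 1761130 lay next to the group of 6 on that arm.

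In whole windows of 1 Mb inside the span of each arm, the number of peaks had a median of 14 (quartiles 10 and 19) over 109 windows. The densest window was 3L from 1 to 2 Mb, with 37 peaks, and it contains the group of 6. It was followed by 2R from 19 to 20 Mb with 30 peaks and 2R from 3 to 4 Mb with 28. The sparsest were 2L from 17 to 18 Mb with 1 peak and X from 12 to 13 Mb with 2. The variance between windows was 2.74 times their mean.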

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

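The excess of peaks with a near neighbour kept its direction and its side of the 0.05 threshold under each of the 7 alternatives run, 3 of them chosen after seeing the data. The share ranged from 21.9% (limit 5 kb) to 84.6% (limit 50 kb), each time above its own random value. In the top 50% of the list by score it was 22.7% against 14.3% at random, and with peaks merged across gaps under 1 kb it was 34.5% against 24.9%. The census moves by construction with a stricter score: the top 50% held 862 peaks with a median width of 1775.5 bp, a median score of 91.2 and 1.75 Mb covered, and the top 25% held 431 peaks with 2026 bp, 114.32 and 0.984 Mb. Merging gave 1630 regions, a median width of 1560 bp, a median score of 69.5 and 3.10 Mb covered. The share of each arm stayed inside the 95% interval of its main value without merging and in the top 50% by score. Counted in covered bases, 1 share left its interval: the X held 12.2%, where peaks were narrower than on the autosomes. The settings fixed beforehand for gene positions, gene lists, motifs and score by position were not run, since they need an annotation or a sequence of Release 5. No paired analysis was possible because 1 list stands for both ChIP replicates, and for the same reason no replicate could be left out. Depth limits all of this: without read counts, a region with no peak cannot be told from one that is covered too thinly to be called.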

Other observations

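Of the tests below, those of the width of peaks on the X, of the number of peaks per window and of the longest stretch without a peak were chosen only after the result was seen, and placement within 1 Mb windows was added after the peak list had been seen but before its result. On 3L the region from 1713417 to 1802916 holds 3 separate groups, with 4, 4 and 6 peaks, whose highest scores are 180.33, 123.37 and 184.45. The longest stretch without a peak on any large arm is on 3R, from 21508101 to 22549633 (1042 kb). The longest on the other arms were 754 kb on 2L, 752 kb on the X, 646 kb on 2R and 509 kb on 3L. Peaks with a neighbour within 10 kb did not score measurably higher than single peaks: the median scores were 68.4 (714 peaks) and 69.3 (1002 peaks), a difference of -0.89 (two-sided permutation p = 0.572). Compared within 5 classes of peak width of equal size the difference was -1.97 (stratified permutation p = 0.296), so whether width explains a higher score had nothing to explain. With each arm's span from first to last peak divided into 5 equal parts, the part nearest to the centromere held 286 of 1305 groups (21.9%), and the following parts held 209, 255, 252 and, farthest from it, 303. Whether peaks are sparse next to the centromere cannot be told from this, because the span starts at the outermost peak and leaves out any empty sequence beyond it. On 2R, whose centromere lies at the low end of the coordinates, the first peak starts at 561995 and the next 646 kb hold no peak. On 3R, whose centromere also lies at the low end, 1 peak has a deposited start of -41, before the first base of the arm. It ends at 2036 and has a score of 139.7.

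The grouping of peaks could in principle come from the peak caller splitting single broad regions. Merging peaks across gaps under 1 kb joined 180 peaks into 87 regions, and the share with a neighbour within 10 kb was then 34.5%, above the upper end of the central 95% of random placement (27.7%), which argues against splitting at that scale as the whole source. Differences in density between regions of 1 Mb or more are argued against as the whole source in the same way: placing peaks at random within their own 1 Mb window gave a central 95% that ended at 30.6%, against 41.6% observed. With both handled together, the excess was smaller. Merged peaks placed within their 1 Mb windows gave a median of 26.4% and a central 95% that ended at 29.1%, against 34.5% observed. Splitting over gaps wider than 1 kb, differences in density over stretches shorter than 1 Mb and uneven coverage by alignable reads stay open. The design holds no second biological condition and no table of the input was analysed here, so no biological explanation was tested.

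The X carried fewer peaks than the autosomes, with 11.6 ± 5.11 (SD, 20 windows of 1 Mb) against 15.6 ± 6.43 (SD, 89 windows). Dealing the windows out at random gave a difference as large with a two-sided permutation p of 0.0094. The adjusted p was 0.026 (Benjamini-Hochberg over 5 comparisons of windows). These were not 5 separate questions. They include the same contrast in 2 Mb windows (permutation p = 0.0311) and without the densest window (permutation p = 0.0104). The test does not exclude chance, since the X was picked as the arm with the lowest density and tested on the same peaks, and neighbouring windows are not independent. Arm 2L was also below the other autosomes, at 12.9 ± 6.26 (SD, 21 windows) against 16.5 ± 6.29 (SD, 68 windows, permutation p = 0.0262, adjusted p = 0.0389). It was likewise picked as the autosomal arm with the lowest density and tested on the same peaks, so chance is not excluded there either. The X was not distinguishable from 2L (permutation p = 0.467). One candidate explanation is the single X of male embryos, which would lower the reads there. The input is from the same chromatin and would have fewer reads on the X as well. How the input entered the calls is not given, so its effect on the X peaks cannot be told. Peaks on the X had a median width of 1320.5 bp against 1560 bp on the autosomes (a difference of -239.5 bp, two-sided permutation p = 0.0007). That is the direction this explanation needs. However, the width test was chosen after the narrower peaks had been seen, and it treats peaks as independent. The median score differed by -0.595 (permutation p = 0.779). Neither result decides, because low scores are missing from the list and width rises with score in it. The single X could not account for a lower number on 2L, if that is more than chance. A true difference in binding between arms stays open and untested.

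For the stretch of 3R without a peak, the distance between the midpoints of the flanking groups was 1043 kb. Random placement of the 1305 groups gave a longest distance on any of the 5 arms as long as this with a one-sided permutation p of 0.0183, and the upper end of its central 95% was 1008 kb. This does not exclude chance, since the placement assumes even density of groups along each arm, which was not tested arm by arm. Over all 5 arms the 5 equal parts held 286, 209, 255, 252 and 303 groups from the centromere outwards, so the counts differed between parts. On 3R they held 67, 48, 72, 67 and 67. These parts of 3R are 5.54 Mb long, too coarse to show the density around a stretch of 1043 kb. The variance between 1 Mb windows, 2.74 times their mean, was of single peaks over all 5 arms. It does not show how evenly groups lie along an arm. The test was also chosen after the stretch had been seen. Density that varies along the arm, absent binding and poor coverage by alignable reads were not tested against each other.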
